A study of Homo sapiens with 45 samples.

How the data were processed

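Total RNA of U2OS cells, a human osteosarcoma line, was measured on 45 single-colour Affymetrix arrays, 1 per sample. Per the labels, 3 derived lines were used, named ERa, ERb and ERab after the estrogen receptors they carry. Each was a control or was treated with E2 (estradiol, the natural estrogen) or 4HT (4-hydroxytamoxifen, the active metabolite of tamoxifen) for 24 h; the label of 1 array, ERa 4HT replicate A, gives no time. Doses are not given in the sources used here, and neither is the upstream processing of the arrays (image analysis and the summary of probes into probe sets).

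The deposited values are linear signal intensities in arbitrary units, in 1 table of 8793 probe sets, of which 47 are control probe sets of the manufacturer. The 2% trimmed mean of every array lies between 1501.3 and 1501.7, so the authors had scaled each array to a common trimmed mean. No further scaling was applied, since the tolerance set for the trimmed means was 10%. No 2 columns are identical, and the highest correlation between 2 arrays is 0.9701. Values were used as log2(value + 16), which understates fold changes of weakly measured genes. A platform annotation of 2016 assigns 1 gene to 7840 probe sets and several to 388, and 518 are not listed in it. No symbol needed updating against the current gene table. Probe sets whose names carry _s_ or _x_ can match several transcripts.

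The labels give array numbers but name no runs. From gaps in the numbers 3 runs were set, an early one (15 arrays, numbers 1 to 24), a middle one (12 arrays, 30 to 41) and a late one (18 arrays, 64 to 81). Within the early run lies a further gap, wider than that before the middle run. Before it come only ERab control and E2 replicates A and B. This block was not modelled, so comparisons of controls cannot fully separate it from the ERab line. Controls of every line are in all 3 runs, E2 in the early and the late run, and 4HT in the middle and the late run. ERa 4HT replicate A has no number and was placed in the middle run, as its letter comes before B and a number of that run is free. Its deviation from the mean of all 45 arrays correlated with those of the ERa controls of that run at 0.402 to 0.412 (early run -0.0645 to -0.0228, late run 0.0228 to 0.0648). Replicate letters often fall in different runs for different ligands, so the main fit did not use them to pair arrays.

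Probe sets were tested if at or above the median of their own array on at least 4 arrays, which left 5347 (4736 genes). All 45 arrays were fitted together in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with trend), with 9 group means and a run term for each line, 15 coefficients and 30 residual degrees of freedom. Contrasts were each ligand against control within a line, 4HT against E2 within a line, and the difference of each ligand's effect between lines. Controls of different lines were compared on the 20 control arrays with a common run term and 15 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of a comparison, and a probe set is called at an adjusted p under 0.05. Number of arrays limits the precision. Nothing in the labels says that arrays are separate cultures, so p-values measure the spread between these arrays, and with 1 line per receptor combination receptor and clone are confounded. No detection calls were used.

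Before the data were examined, 28 gene lists were fixed from general knowledge, and so were the filter, the model, the alternatives and the rule for named genes, except where chosen after seeing the data is stated. The 27 lists with at least 5 tested genes were tested by limma's camera with a preset correlation of 0.01, and again with a correlation estimated from the arrays. Each gene counts once, by its probe set with the highest mean. Fry tested whether a list moved one way or in either direction. Named genes are those with the largest called changes of the same sign in every run, 8 in each direction for a ligand against control and 4 for other comparisons, and up to 4 members per list with the smallest adjusted p. Overlaps of calls were tested by Fisher's exact test, two-sided. Intervals are 95% intervals of the fitted difference.

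Alternatives were no run term, the replicate letter as a block, the late run alone, ERa 4HT replicate A in the early run, pseudocounts of 1 and 64, quantile normalization, no filter, a stricter filter (75th percentile), only the lines compared, an estimated list correlation, and leaving out each array in turn. Means of each group within a run were an alternative chosen after seeing the data. The procedure was tested on simulated data, in which a true log2 change of 1 was called for 89.6 to 94% of changed probe sets and one of 0.5 for 37.3 to 62.7%. Unchanged probe sets made up 3.53 to 8.43% of the calls there, and 6 of 200 unchanged lists had a p under 0.05. Noise was drawn independently for each probe set, so the simulation does not test lists of correlated genes.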

Results

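Transcript levels were measured in U2OS osteosarcoma cells that carry estrogen receptor alpha (ERa), beta (ERb) or both (ERab), after 24 h with E2, with 4HT, or as controls. The ERa line had 6 control, 4 E2 and 4 4HT arrays. The ERb line had 7, 4 and 4, and the ERab line 7, 5 and 4. The questions named by the labels are what each ligand changes in each line and how the lines and ligands differ. Array medians ranged from 461.9 to 664.8 intensity units after the authors' scaling. They depended on the run, with a mean of 628 ± 21.2 (SD) in the early run, 515 ± 32.9 in the middle run and 511 ± 14.3 in the late run. The probe set of ESR1, the gene of ERa, read 61.8 to 539.5 over all arrays and that of ESR2, the gene of ERb, 3.6 to 94.1. On no array did either reach the array median, so neither was tested and receptor expression could not be read from them. ESR1 read 251.9 ± 65.5 (SD, n = 6) in ERa controls and 282.9 ± 110.9 (n = 7) in ERb controls.

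In ERa cells E2 raised MUC1, a cell-surface mucin used as an epithelial marker, from 671 ± 105.8 (SD, n = 6) to 16960 ± 2818 (n = 4). MATN1, the cartilage matrix protein matrilin-1, rose from 609.4 ± 104.2 to 22170 ± 1534, a log2 change of 5.28 (SE 0.40). CYP1A1, an oxidase of foreign compounds and estrogens, rose by a log2 change of 3.85 (SE 0.29). GABRD, OTOF, DUOX2, TERT (the catalytic subunit of telomerase) and FGFR3 rose by 3.41 to 3.83. INHBA, a subunit of activin, fell from 5195 ± 1434 to 431.5 ± 265.8, with log2 changes of -4.68 in the early and -3.27 in the late run. GPRC5A, TGFBI, ANXA10, EMP1, RASGRP1, ID1 and the growth regulator MYC had log2 changes from -3.43 to -2.41. EMP1 changed by -4.00 in the early and -1.37 in the late run.

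By list, 15 of 35 tested estrogen receptor target genes rose and 7 fell with E2 in ERa cells (17 and 7 adjusted over the list alone). CELSR2 rose by 2.23 (log2, SE 0.14) and ABCA3, a lipid transporter, by 2.17 (SE 0.18). MYC and IRS1, an adaptor of insulin receptor signalling, fell by 2.41 and 2.27. Camera gave the list an adjusted p = 0.0136, and p = 0.03 with an estimated correlation. Retinoid and steroid metabolism genes were higher (6 of 14 rose and 2 fell; 10 and 2 adjusted over the list alone), with CYP1A1 and RBP4, a retinol carrier (log2 2.74, SE 0.42), up and CYP24A1 down (-1.69, SE 0.35). This list also had p = 0.0136, and 0.03 with an estimated correlation. TGF-beta and BMP pathway genes were lower, with 12 of 27 down and 5 up (13 and 5 adjusted over the list alone; adjusted p = 0.0376). ID1 fell by 2.55 (SE 0.11) and CCN1 by 2.19 (SE 0.14), while LTBP1 rose by 1.79 (SE 0.14). That call was lost, at adjusted p = 0.0536 with an estimated correlation.

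Cytoskeleton and contractile genes, integrins and other adhesion genes, and S phase genes were also lower with E2 in ERa cells by camera, each at adjusted p = 0.0136. Their calls were lost with an estimated correlation, at adjusted p = 0.113, 0.125 and 0.202 with an estimated correlation. In the cytoskeleton list 14 of 29 fell and 4 rose (14 and 4 adjusted over the list alone), among them the keratin KRT8 and vimentin (VIM), with log2 changes of -0.92 and -1.11. Of 18 adhesion genes 10 fell and 2 rose (10 and 2 adjusted over the list alone). ITGA6, an integrin subunit, fell by 1.97 (SE 0.18) and ALCAM by 1.40 (SE 0.13). Of 29 S phase genes 10 fell, including the replicative helicase subunit MCM2 (log2 -0.47, SE 0.10), and 1 rose, GINS2 (13 and 1 adjusted over the list alone). In all 1564 of 5347 probe sets were called, 633 higher and 931 lower, and 1549 had the same sign in both runs that hold E2. The fitted change pools these runs, so for called probe sets such agreement is largely fixed in advance. Here and for the other lines and 4HT it is not a replication. With the late run alone 936 were called, and DUOX2 lost its call (log2 2.41, adjusted p = 0.0837).

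In ERb cells E2 raised PDZK1, a scaffold protein of membrane transporters, from 156.4 ± 85.1 (SD, n = 7) to 1425 ± 167.6 (n = 4). CHST8, OTOF and the inflammasome sensor NLRP3 rose by log2 changes of 2.98 to 3.09. The cystatins CST5 and CST1, the exonuclease ISG20 and LOX, which crosslinks collagen, rose by 2.49 to 2.67. TGFB2, a TGF-beta ligand, fell from 1239 ± 241.1 to 194.6 ± 41.14, a log2 change of -2.61 (SE 0.21). SMAD6, an inhibitor of BMP signalling, F2R, THBS1, PDGFRB, S100A4, LOXL1 and EFNB3 had changes from -2.49 to -2.15.

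Estrogen receptor target genes were higher with E2 in ERb cells: 17 of 35 rose and 5 fell (18 and 5 adjusted over the list alone; adjusted p = 1.18e-05, and 0.000344 with an estimated correlation). ABCA3 rose by 2.42 (SE 0.17), the carbonic anhydrase CA12 by 1.63 (SE 0.12) and KLRC3 by 2.40 (SE 0.26). NF-kappaB and cytokine genes were higher too, with 7 of 14 up and 2 down (7 and 2 adjusted over the list alone; adjusted p = 0.00912, and 0.0241 estimated). TRAF1 rose by 1.91, RELB by 1.26 and NFKBIA, the inhibitor of NF-kappaB, by 0.96. Of 16 unfolded protein response genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; 6 and 1 unadjusted), among them PPP1R15A and XBP1 (log2 0.72 and 0.49; adjusted p = 0.0223, and 0.0361 estimated). Extracellular matrix genes were lower, with 9 of 22 down and 3 up (10 and 3 adjusted over the list alone; adjusted p = 0.00859, and 0.0349 estimated). THBS1 fell by 2.43 (SE 0.28) and the collagen COL4A1 by 0.81 (SE 0.09). TGF-beta and BMP pathway genes were lower as well: 12 of 27 fell and 5 rose (12 and 6 adjusted over the list alone; adjusted p = 0.0137, and 0.0241 estimated). LTBP2 fell by 1.30, whereas CCN2 rose by 0.80.

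The S phase and mitotic lists shifted upward relative to other genes with E2 in ERb cells by camera with the preset correlation, at adjusted p = 0.00453 for each list. With an estimated correlation both calls were lost, at adjusted p = 0.115 and 0.172 with an estimated correlation. Of 29 S phase genes 9 rose (10 adjusted over the list alone, 13 at an unadjusted p under 0.05, none lower on any of these counts), including MCM5 (log2 0.50, SE 0.10) and RRM2, a subunit of ribonucleotide reductase (0.35, SE 0.07). Of 32 mitotic genes 6 rose (6 adjusted over the list alone, 12 unadjusted, none lower), among them the kinase PLK1 (0.59, SE 0.09). Wnt pathway and cytoskeleton genes were lower, at adjusted p = 0.025 and 0.0495. These calls were lost too, at adjusted p = 0.0804 and 0.172 with an estimated correlation. Of 18 Wnt genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with WNT5A at -1.20 (SE 0.17). Of 29 cytoskeleton genes 11 fell and 3 rose (13 and 4 adjusted over the list alone), and the tropomyosin TPM1 fell by 1.04 (SE 0.10). Altogether 1132 probe sets were called, 555 higher and 577 lower, 1125 of them with the same sign in both runs. The late run alone gave 574 calls and a fit without a run term 581, and in the former PDGFRB and SMAD6 lost their calls (adjusted p = 0.0857 at most).

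In ERab cells E2 raised RBP4 from 88.74 ± 62.09 (SD, n = 7) to 2651 ± 127.1 (n = 5), a log2 change of 5.16 (SE 0.38) that was 5.36 within the early and about 5 within the late run. CYP4F11, a fatty acid hydroxylase, rose by 3.95 (SE 0.45) from a control level of 24.1, near the bottom of the scale. ETFB, a subunit of the mitochondrial electron transfer flavoprotein, rose from 2268 ± 720.2 to 21190 ± 6259. OTOF, TERT, GABBR2, the peroxisomal oxidase ACOX2 and ABCA3 rose by 3.23 to 3.85. The growth factor BMP4 fell from 1888 ± 523 to 178.3 ± 130.1, a log2 change of -3.84 (SE 0.24) that was -4.46 in the early and -2.55 in the late run. LYPD1, GPRC5A, ANXA10, TGFB2, CSRP3, the tight junction protein CLDN4 and ACACA, which makes malonyl-CoA for fatty acid synthesis, had changes from -2.92 to -2.49.

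Estrogen receptor target genes rose in ERab cells with E2, 18 of 35 up and 4 down (19 and 4 adjusted over the list alone; adjusted p = 0.000182, and 0.00171 with an estimated correlation). CA12 rose by 1.57 (SE 0.11) and TPBG by 1.46 (SE 0.12), while MYC fell by 2.13 (SE 0.14). In the TGF-beta and BMP pathway 14 of 27 fell and 4 rose (15 and 4 adjusted over the list alone; adjusted p = 0.00657, and 0.00708 estimated). TGIF1 fell by 1.26 and ID1 by 1.32, and LTBP1 rose by 2.24. Of 29 cytoskeleton genes 16 fell and 3 rose (16 and 3 adjusted over the list alone; adjusted p = 0.00657). TPM1 fell by 1.16 and KRT18 by 0.82, and the tubulin TUBA1A rose by 1.04. This last call was lost, at adjusted p = 0.0782 with an estimated correlation. In this line 1777 probe sets were called, 735 higher and 1042 lower, 1772 with the same sign in both runs. Calls numbered 1172 in the late run alone and 1157 without a run term.

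**Figure D1:**
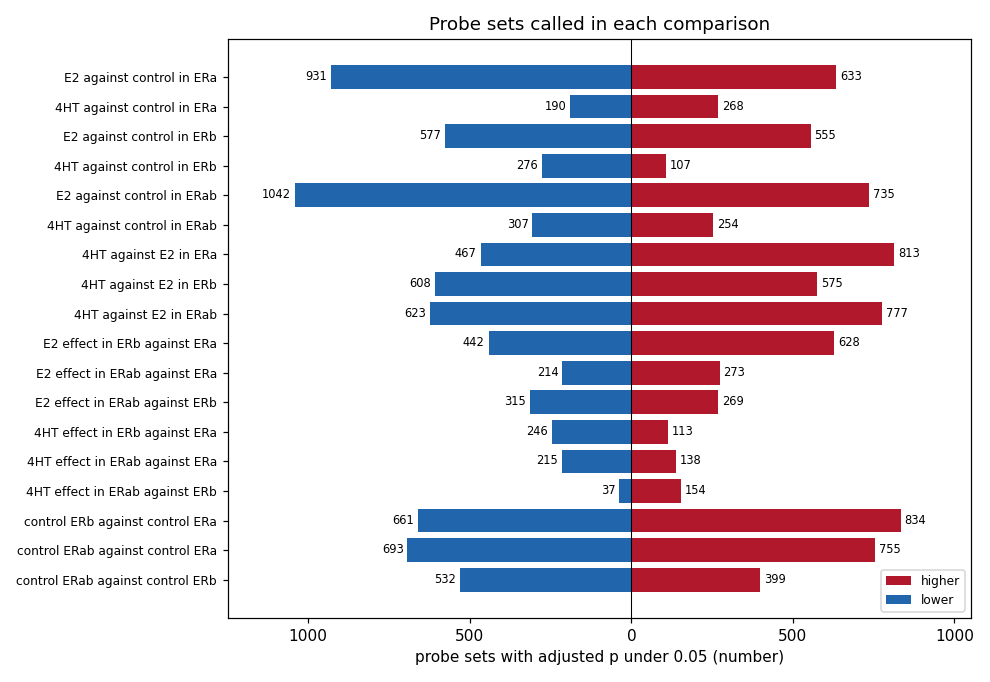
Number of probe sets called (adjusted p under 0.05, of 5347 tested) in each of the 18 comparisons; bars to the right count higher and bars to the left lower probe sets. E2 against control called 1564, 1132 and 1777 probe sets in ERa, ERb and ERab, and 4HT 458, 383 and 561.

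Changes with E2 overlapped between the lines. ERa and ERab shared 959 calls of the same direction and 40 of opposite direction, ERb and ERab 690 and 31, and ERa and ERb 463 and 121. For calls raised in ERa and in ERb 219 were shared, against 65.7 with independent lists (Fisher's exact test, two-sided, p = 7.98e-73, which treats probe sets as independent). Among the genes raised in all 3 lines were KRT19, an epithelial keratin, by 1.94 (SE 0.30), 1.73 (SE 0.29) and 1.99 (SE 0.27) in ERa, ERb and ERab. ABCA3 and TFF1, a secreted trefoil peptide, were likewise raised in each line, TFF1 by 0.74, 1.27 and 1.41. The endothelial marker VWF also rose in all 3, by 2.37 (SE 0.28) in ERa and 1.01 (SE 0.26) in ERb. Across all probe sets, which are not independent replicates, E2 changes correlated at r = 0.692 for ERa with ERab, 0.591 for ERb with ERab and 0.314 for ERa with ERb. Shared calls of ERa and ERb numbered 228 with the late run alone and 250 without a run term.

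4HT in ERa cells raised CYP4F11 by 2.81 (log2, SE 0.50), CDO1, which oxidizes cysteine, by 2.47 (SE 0.19) and LPL, lipoprotein lipase, by 1.71 (SE 0.12). LPL went from 1017 ± 148.7 (SD, n = 6) to 3276 ± 293.9 (n = 4). CHRM4, ARID3B, FGFR3, LGALS14 and the troponin gene TNNC1 rose by 1.76 to 2.12. The keratins KRT15 and KRT19 had log2 changes of -3.66 (SE 0.27) and -2.50 (SE 0.30), KRT19 going from 8604 ± 1143 to 1637 ± 617.7. PRKCZ, PADI4, MPPED1, ARRB1, the cytokine IL24 and DECR1, an enzyme of fatty acid oxidation, had log2 changes from -2.77 to -1.75.

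The S phase and mitotic lists shifted upward relative to other genes with 4HT in ERa cells by camera, at adjusted p = 1.03e-05 and 1.79e-06. Both calls were lost, at adjusted p = 0.0734 with an estimated correlation for each list. Of 29 S phase genes 9 rose (12 adjusted over the list alone, 14 unadjusted, none lower), such as MCM6 (0.50, SE 0.11). Of 32 mitotic genes 7 rose (14 adjusted over the list alone, 17 unadjusted, none lower), such as BUB1B (0.49, SE 0.11). Adhesion genes were lower (4 of 18 down, 1 up; 6 and 1 adjusted over the list alone; adjusted p = 0.0339, and adjusted p = 0.18 with an estimated correlation). NCAM1 fell by 1.20 and ITGA6 by 0.98, and SDC4 rose by 0.51. In the list of 7 epithelial markers, which does not hold KRT19, KRT15 alone was called (also adjusted over the list alone; adjusted p = 0.0471 for the list, and adjusted p = 0.0803 with an estimated correlation). Calls numbered 458, with 268 higher and 190 lower, and 457 had the same sign in both runs that hold 4HT. With the late run alone 144 were called (204 without a run term), and ARID3B, CYP4F11, FGFR3, IL24 and MPPED1 lost their calls. FGFR3 changed by 3.07 in the middle and 0.68 in the late run, and its change was 1.48 without ERa 4HT replicate B (adjusted p = 0.057) and 2.58 without ERa 4HT replicate C.

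In ERb cells 4HT lowered KRT19 from 1909 ± 687.2 (SD, n = 7) to 78.18 ± 112.2 (n = 4), with log2 changes of -6.00 in the middle and -3.83 in the late run. RET, a receptor tyrosine kinase, fell by 3.49 (SE 0.32), KRT15 by 3.36 (SE 0.27) and KLRC3 by 3.16 (SE 0.27). MPPED1, IL24, the keratin KRT13 and PADI4 had changes from -3.10 to -2.34, with MPPED1 at -2.37 without ERb 4HT replicate D. Fewer called probe sets rose over 2-fold (8) than fell over 2-fold (90). The keratin KRT7 rose from 136.1 ± 62.04 to 959.2 ± 394.8, a log2 change of 2.42 (SE 0.44). CYP24A1, which inactivates vitamin D, rose by 1.43 (SE 0.35), NDRG1 by 1.12 (SE 0.10) and the stress-induced factor ATF3 by 1.08 (SE 0.12). S100A4, PRDM11, DACT1 and IL17RB rose by 1.02 to 1.37. With 1 array left out at a time, the call of S100A4 ended for 9 arrays, that of PRDM11 for 28 and that of IL17RB for 8, at adjusted p of up to 0.143, 0.236 and 0.195.

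Estrogen receptor target genes were lower with 4HT in ERb cells. Of 35 tested, 12 fell and 0 rose (14 and 0 adjusted over the list alone; 16 and 1 at an unadjusted p under 0.05). The list had adjusted p = 2.04e-10, and 1.96e-06 with an estimated correlation. KRT19, KLRC3 and RET were among the 12, and SERPINA1, a protease inhibitor, fell by 1.57 (SE 0.12). TGF-beta and BMP pathway genes were lower (5 of 27 down, 1 up; 10 and 2 adjusted over the list alone; adjusted p = 0.0302, and 0.0345 estimated), with INHBA at -1.84 (SE 0.24) and FST, which binds activin, at -1.02 (SE 0.16). Of 383 probe sets called, 107 were higher and 276 lower, and all 383 had the same sign in both runs, which the pooled fit makes likely. The late run alone gave 195 calls, and there DACT1, KRT7, PADI4, PRDM11 and S100A4 lost their calls. Without ERb 4HT replicate C the DACT1 change was 0.95 (adjusted p = 0.127).

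In ERab cells 4HT raised LORICRIN, a protein of the cornified envelope of skin cells, from 326.3 ± 128.8 (SD, n = 7) to 11430 ± 2664 (n = 4), by 4.95 in the middle and 4.50 in the late run (log2). IVL, or involucrin, another component of that envelope, rose from 1836 ± 1016 to 14210 ± 2095. RBP4 rose by 4.66 (SE 0.42), the aromatase gene CYP19A1 by 2.03 (SE 0.40) and S100A9 by 1.98 (SE 0.24). FGFR3, GABBR2 and ANXA9 rose by 1.86 to 2.10. KRT19 fell by 2.92 (SE 0.30), and GJA1, the gap junction protein connexin 43, from 7812 ± 3270 to 1137 ± 504.4. MPPED1, ARRB1, KRT15, BMP4, the coagulation factor F13A1 and IL24 had changes from -2.67 to -2.17. BMP4 changed by -2.93 in the middle and -1.04 in the late run. By camera 0 of 27 lists were called in this comparison, also with an estimated correlation, while 7 had an unadjusted p under 0.05 and by fry 14 did. Among the 7 were the estrogen receptor target genes (10 of 35 lower and 4 higher, adjusted p = 0.0721). Of 561 probe sets called, 254 were higher and 307 lower, and 559 had the same sign in both runs. From the late run alone 238 were called, and ANXA9 and FGFR3 lost their calls. The ANXA9 call also ended without ERab 4HT replicate A, ERab 4HT replicate C or ERab control replicate D, at changes of 1.76, 1.80 and 1.87 (adjusted p = 0.0687, 0.0683 and 0.0504).

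Calls with 4HT were shared in the same direction by 164 probe sets of ERb and ERab (8 opposite), 135 of ERa and ERab (16 opposite) and 87 of ERa and ERb (34 opposite). Lowered calls made up most of the overlap of ERb and ERab, with 130 shared against 15.8 for independent lists (Fisher's exact test, two-sided, p = 5.2e-96). KRT19, KRT15, IL24, MPPED1, PADI4 and ARRB1 fell in all 3 lines. MPPED1 fell by 1.95, 3.10 and 2.67 in ERa, ERb and ERab (2.37 in ERb without ERb 4HT replicate D). Of these 4 were not called with E2 in ERa cells: KRT15 (-0.42, SE 0.27), IL24 (-0.54, SE 0.29), MPPED1 (0.28, SE 0.32) and PADI4 (0.58, SE 0.55). Across probe sets the 4HT changes correlated at r = 0.41, 0.281 and 0.187 for these 3 pairs of lines. In the late run alone the shared calls numbered 77, 53 and 38.

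**Figure D2:**
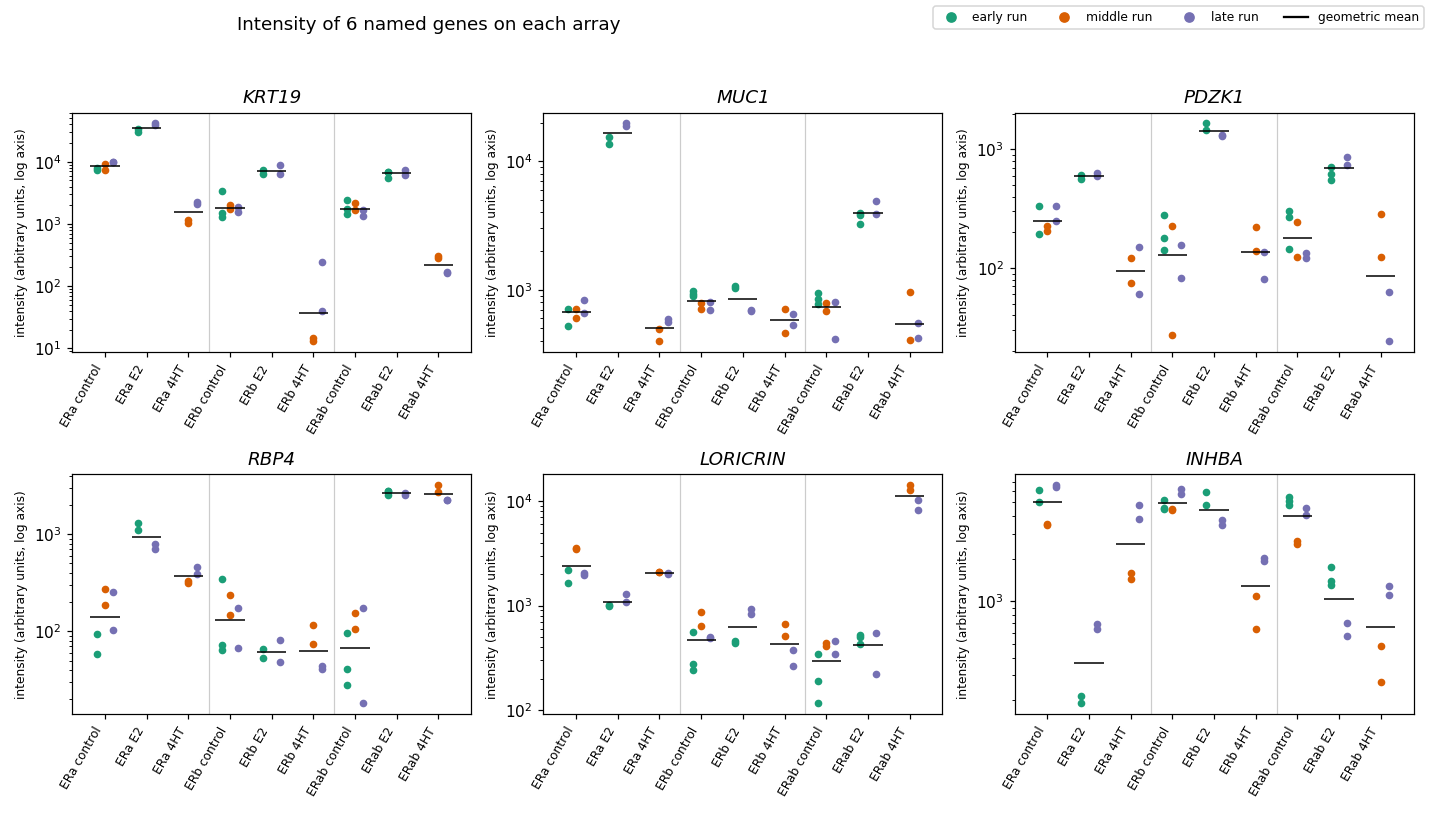
Intensity (arbitrary units, log axis) of KRT19, MUC1, PDZK1, RBP4, LORICRIN and INHBA on each array of the 9 groups; points are arrays, colours are runs, and lines are geometric means. KRT19 reads 30170 to 41310 in ERa cells with E2 and 12.9 to 245.4 in ERb cells with 4HT, and LORICRIN reads 8248 to 14192 in ERab cells with 4HT and at most 3553 in every other group.

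Within a line the ligands were compared by the overlap of their changes, which share control arrays. In ERa cells 195 probe sets were called with both ligands in the same direction and 74 in opposite directions, and in ERab cells 195 and 145. In ERb cells the balance was the other way, with 44 in the same and 169 in opposite directions. There 131 probe sets were raised by E2 and lowered by 4HT, against 28.6 for independent lists (Fisher's exact test, two-sided, p = 6.31e-60). By the same Fisher's exact test the class held 43 against 22.5 in ERa (p = 1.75e-05) and 93 against 42.2 in ERab (p = 8.06e-15). Among the 131 were KRT19, KRT15, IL24 and KLRC3, with log2 changes of 1.73, 1.47, 2.40 and 2.40 with E2 and -4.87, -3.36, -2.92 and -3.16 with 4HT (KRT19 -5.58 without ERb 4HT replicate C). Their means with 4HT lay under the lowest lower quartile of any array, so the exact sizes of these falls are uncertain. Across all probe sets r between the ligands' changes was 0.232 in ERa, -0.182 in ERb and 0.107 in ERab. Shared controls alone gave simulated mean r of 0.278, 0.281 and 0.254, in data with no ligand effect, so these cannot be set against the observed r. Covariances were 0.0461, -0.0294 and 0.0232, against simulated means of 0.012, 0.0116 and 0.00979. Changes from runs with no array in common (E2 early, 4HT middle) gave r = 0.174, -0.195 and 0.0727. In the late run alone 60, 20 and 76 probe sets were called with both ligands in the same direction in ERa, ERb and ERab.

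**Figure D3:**
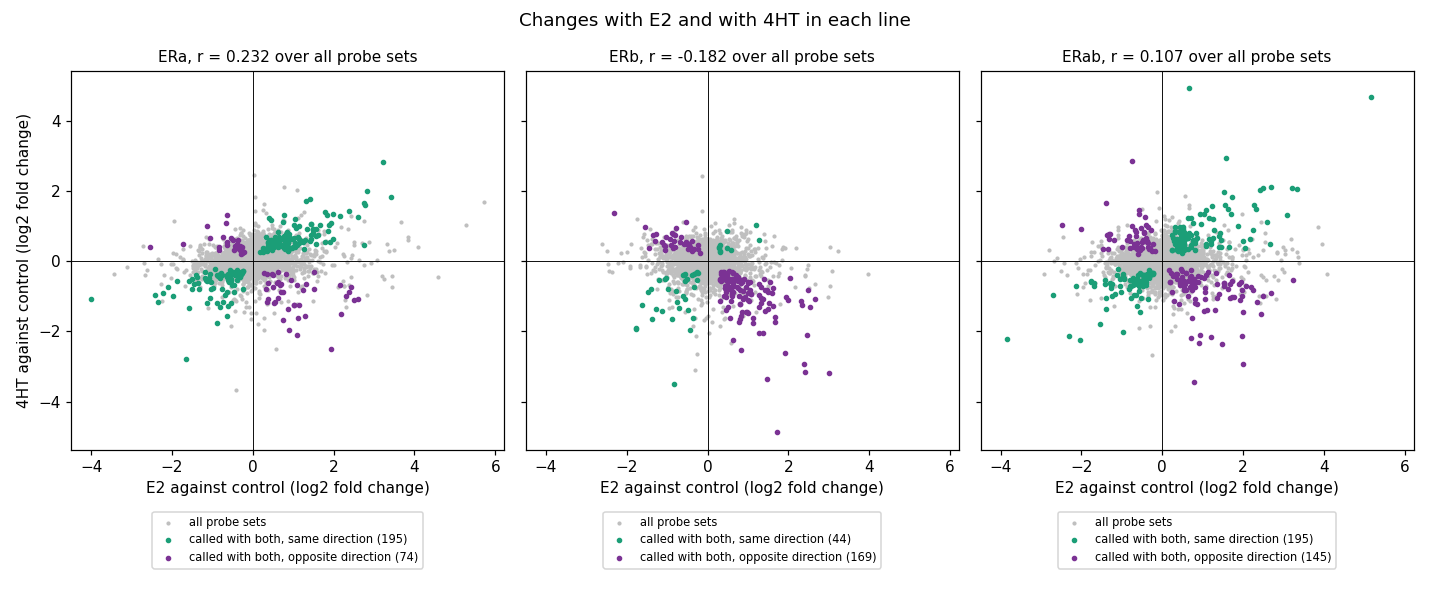
Log2 change with 4HT (vertical) against log2 change with E2 (horizontal) of each of 5347 probe sets in ERa, ERb and ERab; green and purple points are called with both ligands in the same and in opposite directions. The numbers are 195 and 74 in ERa, 44 and 169 in ERb, and 195 and 145 in ERab.

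Set directly against E2, 4HT left MUC1 lower in ERa cells, with a log2 difference of -5.05 (SE 0.22) and 508.6 ± 85.85 (SD, n = 4) under 4HT. KRT19, MATN1 and TERT had differences from -4.44 to -4.17 there, and TGFBI, CSRP3, GPRC5A and ID1 from 2.95 to 3.15. In ERb cells KRT19, KLRC3, IL24 and KRT15 were lower with 4HT than with E2, with differences from -6.60 to -4.83. S100A4, TGFB2, SMAD6 and KRT7 were higher, from 2.56 to 3.68. The 4HT means of KRT19, KLRC3, IL24 and KRT15 lay under the lowest lower quartile of any array (130.8). The exact sizes and the order of their differences are therefore uncertain. Between the lowest and the highest pseudocount, KLRC3 moved from -6.298 to -4.485 and IL24 from -5.581 to -4.727. In ERab cells KRT19, SLC6A3, a dopamine transporter, BCR and CMKLR1 had differences from -4.92 to -3.89, and LORICRIN, IVL, CLDN4 and EDN2 from 3.16 to 4.26. Without ERa E2 replicate D the differences were 2.46 for CSRP3 and 3.66 for GPRC5A, and without ERab 4HT replicate D that of BCR was -3.21. In ERb, KRT19 differed by -7.47 without ERb 4HT replicate C, and SMAD6 by 2.20 and 3.38 without ERb E2 replicate C and ERb E2 replicate D. Doses are not given, so the ligands cannot be placed on a common scale. Called probe sets numbered 1280 in ERa (813 higher with 4HT, 467 lower), 1183 in ERb (575 and 608) and 1400 in ERab (777 and 623).

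Some large changes were alike in size with both ligands, within intervals that remain wide. RBP4 in ERab cells changed by 5.16 with E2 and 4.66 with 4HT, a difference of -0.49 (95% interval -1.47 to 0.48). For CYP4F11 in ERa cells the difference was -0.42 (-1.62 to 0.78), and for GJA1 in ERab cells -0.21 (-0.53 to 0.10). INHBA in ERa cells fell with both ligands but less with 4HT, the difference being 2.94 (2.37 to 3.52), and LORICRIN in ERab cells rose more with 4HT (4.26, 3.67 to 4.85). Of the 195 probe sets called with both ligands in the same direction in ERa cells, 75 also differed between the ligands. In ERb cells 11 of 44 did, and in ERab cells 58 of 195.

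Estrogen receptor target genes were lower with 4HT than with E2 in each line. Of 35 tested, 9 were lower and 5 higher in ERa (10 and 5 adjusted over the list alone), 19 and 1 in ERb (21 and 2), and 18 and 4 in ERab (20 and 5). The adjusted p was 0.00116, 2.4e-12 and 8.47e-06, and 0.00448, 3.63e-07 and 0.000286 with an estimated correlation. ABCA3 differed by -2.85 in ERa and -3.76 in ERab, and CA12 by -2.89 in ERb. NF-kappaB and cytokine genes were also lower in ERb (6 of 14, 1 higher; 8 and 1 adjusted over the list alone; adjusted p = 0.000977, and 0.00373 estimated) and in ERab (8, 1 higher; 8 and 2 adjusted over the list alone; adjusted p = 0.0266, and 0.0436 estimated). NFKBIA differed by -2.42 in ERb cells. TGF-beta and BMP pathway genes were higher with 4HT in ERa (13 of 27, 4 lower; 14 and 4 adjusted over the list alone; adjusted p = 0.00264, and 0.00448 estimated) and in ERab (13, 3 lower; 13 and 3 adjusted over the list alone; adjusted p = 0.0219, and 0.018 estimated). ID1 differed by 2.95 in ERa and 2.09 in ERab. In ERa cells 21 of 29 S phase genes were higher with 4HT (21 adjusted over the list alone, with 1 lower; 22 higher and 1 lower unadjusted), such as MCM6 by 0.90 (SE 0.13). Their adjusted p was 7.47e-07, and 0.009 with an estimated correlation. With an estimated correlation the remaining list calls were lost except for growth factor genes in ERab cells (7 of 16 higher with 4HT and 2 lower; 10 and 2 adjusted over the list alone; adjusted p = 0.0266, and 0.0436 estimated), among them FGFR1 and FGFR2 by 1.68 and 1.76. The lost calls included mitotic genes in ERa (13 of 32 higher and 0 lower; 16 and 0 unadjusted; adjusted p = 0.00304, and adjusted p = 0.15 with an estimated correlation) and Wnt pathway genes in ERa (8 of 18 higher, 1 lower; adjusted p = 0.0248, and adjusted p = 0.0545 with an estimated correlation). Cytoskeleton genes in ERab were also lost (14 of 29 higher, 5 lower; adjusted p = 0.0266, and adjusted p = 0.112 with an estimated correlation). The endothelial marker VWF was lower with 4HT than with E2 by differences of -3.24 in ERa and -3.49 in ERab (-2.88 without ERab 4HT replicate D).

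The difference of E2's effect between lines was tested as an interaction. MUC1 changed by 4.59 (SE 0.19) in ERa, 2.44 (SE 0.17) in ERab and 0.03 (SE 0.18) in ERb, and MATN1 by 5.28, 1.34 and 0.21. INHBA changed by -4.01 in ERa and -0.37 in ERb, an interaction of 3.64 (SE 0.33). NLRP3 and IL24 changed by 2.98 and 2.40 in ERb and by -0.48 and -0.54 in ERa, with interactions of 3.47 and 2.94. TGFBI differed by 2.59, FGFR3 by -3.71 and DUOX2 by -3.88 (ERb minus ERa). RBP4 changed by 2.74 in ERa, -0.74 in ERb and 5.16 in ERab, and the ERab effect differed from both, by 2.42 and 5.90. Likewise ACOX2 changed by 3.33 in ERab and 0.93 in ERa, an interaction of 2.40. Its ERab controls (175.5) were far below its ERa controls, as given for controls below, so the larger rise need not end at a higher level. BMP4 changed by -3.84 in ERab and -1.26 in ERb, an interaction of -2.58. It changed by -0.10 in ERa (interaction of -3.74), but from 84.22 ± 22.96, below the lower quartile of every array (130.8 to 220.2), which left little room to fall. FOS, an immediate early gene, differed by 3.05 between ERab and ERb, at 2.32 and -0.72, and DPEP3 by 3.26 and FGFR3 by 2.99. In ERb with E2 the means of FOS (60.38), DPEP3 (63.1), FGFR3 (65.28), RBP4 (62.5) and DUOX2 (50.05) were also below the lower quartile of every array. So were FGFR3 in ERa controls (47.47), NLRP3 in ERb controls (102), TGFBI in ERa with E2 (87.75) and RBP4 in ERab controls (88.74). The exact sizes of these interactions are therefore uncertain. SRC, a tyrosine kinase, changed by 2.27 in ERab and -0.40 in ERa, and OVGP1 and IMPA2 by -0.04 and -0.86 against 2.32 and 1.66. IL13RA2 differed by 2.25 between ERab and ERa, and INHBA, SLC20A2 and CSRP3 between ERab and ERb by -1.94, -1.94 and -2.08.

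S phase genes had higher E2 effects in ERb than in ERa: 18 of 29 were called higher and 1 lower (20 and 1 adjusted over the list alone; adjusted p = 1e-05, and 0.0308 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, changed by 0.41 in ERb and -0.52 in ERa, and MCM3 by 0.32 and -0.44. The list's median difference was 0.613 within the early and 0.518 within the late run. Heat shock and chaperone genes differed the same way, 8 of 18 higher and 0 lower (8 and 0 adjusted over the list alone; 9 and 0 unadjusted; adjusted p = 0.0205, and 0.0308 estimated). HSPB1 changed by -0.78 in ERa and 0.18 in ERb. In ERab these genes differed from ERa as well (6 higher and 1 lower, as adjusted over the list alone; adjusted p = 0.0144, and 0.0205 estimated), with BAG1 at 2.05 against 0.69. Against ERb, S phase genes had lower E2 effects in ERab (8 of 29 lower, 0 higher; 12 and 0 adjusted over the list alone; 14 and 0 unadjusted; adjusted p = 0.000692, and adjusted p = 0.143 with an estimated correlation). Interactions were called for 1070 probe sets between ERb and ERa, 487 between ERab and ERa and 584 between ERab and ERb. With the late run alone the numbers were 436, 133 and 299, and without a run term 540, 144 and 200. In the late run alone DUOX2 (ERb against ERa), RBP4 and IL13RA2 (ERab against ERa) and BMP4, CSRP3, DPEP3 and SLC20A2 (ERab against ERb) lost their interaction calls. The CSRP3 call also ended without ERb E2 replicate B (-1.54, adjusted p = 0.105) and that of SLC20A2 for each of 13 arrays left out in turn (adjusted p of up to 0.103).

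For 4HT, LORICRIN changed by 4.93 (SE 0.25) in ERab, -0.35 (SE 0.25) in ERa and -0.54 (SE 0.25) in ERb, with interactions of 5.29 and 5.48. IVL changed by 2.85 in ERab, 0.99 in ERb and -0.85 in ERa. RBP4 changed by 4.66 in ERab, 1.13 in ERa and -1.03 in ERb, and GABBR2 by 2.07 in ERab and -0.30 in ERa. RBP4 averaged 88.74 in ERab controls and 69.45 in ERb with 4HT, below the lower quartile of every array. RET went from a rise of 1.07 in ERa to -3.49 in ERb, an interaction of -4.56 (SE 0.45), and KLRC3 from 0.19 to -3.16. RET averaged 128 in ERa controls, below the lower quartile of every array, which left little room for a fall in ERa. KRT7 changed by 2.42 in ERb and -0.46 in ERa, and ST3GAL1, a sialyltransferase, by -1.61 and 1.44. NLRP3 changed by 1.61 in ERab and -1.02 in ERb, an interaction of 2.63 (SE 0.51). CYP24A1 and S100A4 changed by 1.43 and 1.37 in ERb and, not called there, by -0.70 and -0.84 in ERa (interactions of 2.13 and 2.22), and CYP4F11 had an interaction of -2.90 there. BMP4, GPSM2 and GALK1, a kinase of galactose, had interactions of -2.77 to -2.35 between ERab and ERa, and CYP4F11 of -2.31. BMP4 in ERa was again below the lower quartile of every array, and without a run term GALK1 lost its call (-2.17, adjusted p = 0.107). Also below that quartile were KLRC3 (49.1), NLRP3 (53.7) and CYP4F11 (21.08) in ERb with 4HT. The same held for S100A4 in ERa with 4HT (98.88) and CYP4F11 in ERab controls (24.1). The exact sizes of these interactions are therefore uncertain. Between ERab and ERb, SLC10A3 differed by 2.43, and EEA1, OXA1L, ADORA2B and BMP4 by -1.42 to -1.001.

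Estrogen receptor target genes had lower 4HT effects in ERb than in ERa (11 of 35 lower, 2 higher; 13 and 3 adjusted over the list alone; adjusted p = 0.000532, and 0.00474 with an estimated correlation). Cyclin D1 (CCND1) changed by -0.85 in ERb and 0.39 in ERa. Against ERb, the same list was higher in ERab (8 higher, 0 lower; 9 and 0 adjusted over the list alone; 11 and 2 unadjusted; adjusted p = 0.000205, and 0.00138 estimated), and TGFA, a ligand of the EGF receptor, changed by 0.82 in ERab and -0.61 in ERb. AP-1 and immediate early genes were higher in ERab than in ERb (4 of 20, 0 lower; 7 and 0 adjusted over the list alone; 8 and 1 unadjusted; adjusted p = 7.4e-05, and 0.00138 estimated), with MAFF, JUNB and FOS differing by 1.35, 1.36 and 2.25. TGF-beta and BMP pathway genes had lower 4HT effects in ERb than in ERa (5 of 27 lower, 0 higher; 7 and 2 adjusted over the list alone; 10 and 2 unadjusted; adjusted p = 0.00223, and 0.00474 estimated). Mitotic genes had lower 4HT effects in ERab than in ERa (8 of 32 lower, 0 higher; 13 and 0 adjusted over the list alone; 16 and 0 unadjusted; adjusted p = 8.09e-08, and 0.0428 estimated). Called interactions numbered 359 for ERb against ERa (113 higher, 246 lower), 353 for ERab against ERa (138 and 215) and 191 for ERab against ERb (154 and 37). In the late run alone they numbered 90, 53 and 46, and KRT7, S100A4 and CYP4F11 (ERb against ERa), RBP4, BMP4, CYP4F11 and GPSM2 (ERab against ERa) and BMP4, SLC10A3, EEA1 and ADORA2B (ERab against ERb) lost theirs. Without a run term they numbered 145, 108 and 98. The call of S100A4 ended without ERa 4HT replicate C (1.80, adjusted p = 0.0855), that of CYP4F11 between ERab and ERa for each of 13 arrays left out in turn (adjusted p of up to 0.102) and that of BMP4 between ERab and ERb for each of 4 (up to 0.0909).

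Control cells of the lines differed before any ligand. BMP4 read 84.22 ± 22.96 (SD, n = 6) in ERa, 5371 ± 1135 (n = 7) in ERb and 1888 ± 523 (n = 7) in ERab. CXCL8, the neutrophil chemokine interleukin 8, read 1925 ± 1055 in ERa, 99.31 ± 84.87 in ERb and 119.9 ± 79.38 in ERab. SMAD6, ID4 and RET were higher in ERb than in ERa by 4.02, 3.24 and 3.08 (log2), and CA2, CST1 and IL13RA2 had differences from -3.59 to -3.50. In ERab against ERa, CSRP3, ALPP and MARCO were higher by 2.27 to 2.68, and CST1, LORICRIN and ACOX2 had differences from -3.53 to -2.82. IL13RA2, ANKRD2 and GLIPR1 were higher in ERab than in ERb by 1.73 to 2.18. VWF, an endothelial marker, read 1000 ± 198.2 in ERab and 226 ± 133.2 in ERb, and SMAD6, EDIL3, ID4 and the collagen COL6A3 had differences from -3.22 to -2.11 between these lines.

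TGF-beta and BMP pathway genes were higher in ERb than in ERa controls (15 of 27, 5 lower; 16 and 6 adjusted over the list alone; adjusted p = 0.000147, and 0.0141 with an estimated correlation). They were lower in ERab than in ERb (12 of 27, 0 higher; 12 and 0 adjusted over the list alone; 13 and 0 unadjusted; adjusted p = 7.01e-08, and 0.00169 estimated). NF-kappaB and cytokine genes were lower in ERb than in ERa (9 of 14, 1 higher; 9 and 1 adjusted over the list alone; adjusted p = 3.8e-07, and 0.0141 estimated), with TRAF1 at -3.30 (SE 0.22) and LIF at -1.55 (SE 0.10). Bone matrix and osteoblast genes were higher in ERb than in ERa (6 of 13, 1 lower; 6 and 1 adjusted over the list alone; adjusted p = 0.00542, and 0.0262 estimated). COL1A1, the chief collagen of bone, differed by 1.05 (SE 0.09), and SPARC by 0.84 (SE 0.10). Between ERab and ERb this list was lower (4 of 13, 0 higher; 4 and 0 adjusted over the list alone; 5 and 0 unadjusted; adjusted p = 0.0031, and 0.0229 estimated). AP-1 genes were lower in ERb than in ERa (10 of 20, 2 higher; 11 and 2 adjusted over the list alone; adjusted p = 0.000255, and 0.0409 estimated), with EGR1 at -1.05. In ERab against ERb extracellular matrix genes were lower (8 of 22, 0 higher; 8 and 0 adjusted over the list alone and unadjusted; adjusted p = 0.000906, and 0.0229 estimated), and so were metallothionein and oxidative stress genes (6 of 20, 0 higher; 6 and 0 adjusted over the list alone; 8 and 0 unadjusted; adjusted p = 0.0099, and 0.0267 estimated). Controls gave 1495 calls for ERb against ERa, 1448 for ERab against ERa and 931 for ERab against ERb. In the late run alone there were 684, 573 and 310 (ANKRD2 and IL13RA2 lost their calls between ERab and ERb), and without a run term 880, 712 and 357.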

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

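Chosen only after the result was seen were all tests with other splits of the arrays, the tests of shared control arrays, of receptor activity in control cells and of faster division, and that of array runs for ERab cells. A single array lay far from the rest of its group in 5 of 78 sets of values tested, where chance gives about 1 in 20. The ESR2 probe set read 94.1 in ERa control replicate A and 4.6 to 12.4 in the other 5 ERa controls. CYP4F11 read 197.5 in ERa control replicate F and 24.1 to 88.7 in the others. KRT19 read 3370 in ERb control replicate C against 1276 to 1995, and 245.4 in ERb 4HT replicate C against 12.9 to 40. The ratio of the 3' to the 5' probe set of ACTB, a sign of RNA quality, was 1.55 in that same ERb 4HT replicate C and 0.949 to 1.02 in the other 3. Without this array KRT19 changed by -5.58 with 4HT in ERb cells, against -4.87 with it.

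Effects of a ligand differed between lines by the test of the difference itself. For E2 the calls numbered 1070 (ERb against ERa), 487 (ERab against ERa) and 584 (ERab against ERb), and for 4HT 359, 353 and 191. Among 3399 probe sets outside the filter, which the comparisons do not use, E2 against control called 125 in ERa, 72 in ERb and 113 in ERab. The numbers for 4HT were 11, 21 and 20.

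In ERb cells 4HT lowered probe sets that E2 raised, KRT19 and IL24 among them. Shared control arrays push both changes the same way (simulated mean r of 0.281 in ERb), so they could not produce this pattern. E2 and 4HT changes from runs with no array in common correlated across probe sets at -0.195, -0.2 and -0.18, though these pairs of runs reuse some arrays. Scaling differences that quantile normalization removes are argued against, with 129 such probe sets after it and 28.2 for independent lists. Like the authors' scaling it makes arrays alike as a whole, so a real shift of all signals cannot be tested by it. Receptor activity in control cells that 4HT removes stays open: probe sets lowered over 2-fold by E2 in the early run (162) and in the late run (130) had median 4HT changes of 0.148 and 0.17 in the middle run, but all 577 lowered by E2 had a median of 0.02, with 38 called higher and 34 lower with 4HT (11.5 and 29.8 for independent lists). No array without receptor was measured.

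With 4HT, 53 probe sets, LORICRIN among them, changed more positively in ERab than in both other lines, 10 more negatively, 0 above ERa and below ERb, and 9 the reverse. Array runs are argued against: 42 probe sets chosen in the middle run had a median excess of 0.637 in the late run (lower quartile -0.108, 73.8% above 0), and all probe sets -0.132. ERab arrays that both differences share stay open, as differences with no array in common correlated across probe sets at 0.052 and 0.0936. A difference between clones unrelated to the receptors cannot be told apart from receptor content for these genes, because only 1 line has both receptors.

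S phase genes had higher E2 effects in ERb than in ERa. Array runs are argued against, with median differences of 0.613 in the early and 0.518 in the late run and 27 of 29 members higher in each. Scaling differences that quantile normalization removes are argued against by a difference of 0.533 with it, while a real shift of all signals cannot be tested this way. Faster division under E2 in ERb stays open: the G2 and mitosis list differed by a median of 0.178, with adjusted p = 0.404 with an estimated correlation. The 2 lines are also separate clones, which was not tested.

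Other splits of the same arrays into groups of the same sizes move arrays between runs. If arrays of different runs can be exchanged, these splits argue against chance for each ligand against control, 4HT against E2 and controls. Splits within runs do so for E2 in ERb and ERab and for controls. For effects compared between lines, the other splits used values without line-by-run levels and the shared ligand effect. The real count used the full values, and arrays of the other ligand kept theirs, so these counts are not alike and decide nothing. At most 100 splits were counted, the real one included. As many calls as in the real split came from 1 of 100 splits for E2 in ERb (real 1132, highest other 631) and in ERab (1777 and 1116), and for 4HT in ERa (458 and 349), ERb (383 and 140) and ERab (561 and 220). For 4HT against E2 they came from 1 of 35 splits in ERa (1280 and 203) and in ERb (1183 and 273) and from 1 of 100 in ERab (1400 and 1068). For the E2 effect they came from 1 of 100 for ERb against ERa (1070 and 432), ERab against ERa (487 and 246) and ERab against ERb (584 and 7). The 4HT effect gave 1 of 100 for ERb against ERa (359 and 219) and ERab against ERa (353 and 240), and 2 for ERab against ERb (191, highest other 302, and 46 in the late run alone). Controls gave 1 of 100 for ERb against ERa (1495 and 693), ERab against ERa (1448 and 863) and ERab against ERb (931 and 335). For E2 in ERa 2 of 100 splits gave as many as the real 1564. The other one, with 2283, put the 4 early-run arrays together and so followed the run, and within the late run the real split gave 936. Among splits that exchange arrays within a run alone, 1 of 60 gave as many calls for E2 in ERb (highest other 594) and in ERab (967). It was 1 of 100 for the E2 effect (217, 31 and 111, lines in the order above), the 4HT effect (241, 28 and 20) and controls (1075, 863 and 335). E2 in ERa and 4HT in ERa, ERb and ERab have 18 such splits (highest other 296, 36, 26 and 106) and 4HT against E2 has 3 (1, 0 and 0), too few for a share under 0.05.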

How the results depend on the processing

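The fit on means of each group within a run and its values were chosen only after the data were seen, and the other alternatives before. No count moved by over 1.5 times with pseudocounts of 1 or 64, quantile normalization, no or a stricter filter, only the lines compared, ERa 4HT replicate A in the early run, or any 1 array left out. Without a run term, calls against control numbered 204 for 4HT in ERa, and 581 and 1157 for E2 in ERb and ERab. The 4HT effect then gave 145 (ERb against ERa), 108 (ERab against ERa) and 98 (ERab against ERb) calls, the E2 effect 540, 144 and 200, and controls 880, 712 and 357. Shared 4HT calls of ERa were 73 with ERab and 55 with ERb, shared E2 calls of ERb were 250 with ERa and 378 with ERab, and calls with both ligands 78 (ERa), 17 (ERb) and 115 (ERab). The late run alone has fewer arrays and gave 936, 574 and 1172 calls for E2 and 144, 195 and 238 for 4HT in ERa, ERb and ERab. In the same order of lines as above, it gave 436, 133 and 299 for the E2 effect, 90, 53 and 46 for the 4HT effect and 684, 573 and 310 for controls. Shared E2 calls were then 228 (ERa and ERb), 582 (ERa and ERab) and 351 (ERb and ERab), shared 4HT calls 38, 53 and 77, and calls with both ligands 60, 20 and 76. With a replicate block the letters are treated as if they paired arrays, which the data do not settle. Deviations of arrays of different ligands with the same letter had a median r of 0.224 within a run (0.283 for any letter). Between runs it was -0.0144 (-0.14 for any letter). The block gave 210 and 1199 calls for 4HT in ERa and ERab, 526 and 1098 for E2 in ERb and ERab, and 2140 for 4HT against E2 in ERab. The E2 effect gave 468, 137 and 154 calls, the 4HT effect 140, 160 and 100, and controls 927 and 517 for ERab against ERa and ERb. Shared calls were 221, 594 and 342 for E2, 51 for 4HT in ERa and ERb, and 82 for both ligands in ERa. Run means gave 253, 232 and 365 for 4HT in ERa, ERb and ERab, 220, 169 and 92 for the 4HT effect, 228 and 298 for the E2 effect in ERab against ERa and ERb, and 899 and 427 for controls of these pairs. Shared 4HT calls of ERa were 80 with ERab and 55 with ERb, and calls with both ligands 113, 19 and 110. Gene list shifts numbered 85 with the preset and 39 with the estimated correlation. Reversed, none with an adjusted p under 0.11, were ALCAM for 4HT against E2 in ERab (-0.00775 without a run term, -0.1508 with the block), CYCS there (-0.1148 and -0.2039), and CYC1 there (0.04347 with the block). For 4HT against E2 in ERb, CDC45 (0.218) and MCM5 (0.05162) reversed in both settings, and in ERa the mitochondrial respiratory chain list (0.1126). The ribosomal protein list reversed for 4HT in ERa (0.02837 with quantile normalization) and for the 4HT effect in ERab against ERb (0.008047 without a run term, 0.1209 with the block, 0.01087 with quantile normalization). HLA-C (0.03897) and NDUFC1 (0.08871) for 4HT in ERab and IGFBP7 for 4HT in ERb (-0.04297) reversed with the block. HSD17B7 for E2 in ERb (-0.05327) and THRA for controls of ERab against ERa (-0.247) reversed in the late run alone. Of 192 results for named genes, calls lost numbered 35 in the late run alone, 17 with the block, 13 with run means and 10 without a run term, and 4 or fewer in each other setting. Genes that the stricter filter leaves out were not counted as lost. The 10 were IL17RB, PRDM11 and S100A4 (4HT in ERb), IL13RA2, CSRP3 and SLC20A2 (E2 effect), and GALK1, BMP4, EEA1 and CYP24A1 (4HT effect). GALK1 also lost its call with the block (-1.59, adjusted p = 0.291). Except for the smaller number of arrays in the late run, the cause was not tested. Signal near the background limits 69 of these 192 results, in which a group mean lies under the lowest lower quartile of any array (130.8). Between pseudocounts of 1 and 64, 26 of the 69 and 0 of the other 123 moved by over 1. Among them were CYP4F11 for E2 in ERab (4.58 and 2.96), FGFR3 for E2 in ERa (3.79 and 2.67), CSRP3 for 4HT against E2 in ERa (3.68 and 2.27), KRT19 for 4HT in ERb (-5.48 and -3.96) and SMAD6 for controls of ERb against ERa (4.75 and 2.97).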

Other observations

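Genes named here were chosen after their values were seen, from the planned tests of differences between lines, and no other test was added. Several genes had E2 effects in ERab cells above those in both other lines. ABCG2, an exporter of drugs, changed by 3.18 (SE 0.24) in ERab, 1.04 in ERa and 1.56 in ERb. PDLIM3 changed by 3.08 (SE 0.11) against 0.98 and 2.03, and BLVRB, a biliverdin reductase, by 1.99 (SE 0.09) against 1.42 and 1.08. The mitochondrial enzyme IDH2 changed by 2.36 (SE 0.13) in ERab, 1.57 in ERa and 0.30 in ERb. In all, 53 probe sets were more positive in ERab than in both other lines and 28 more negative, while 34 were above ERa and below ERb and 31 the reverse. Both differences share the ERab arrays, so no excess is read from these counts. Other genes went in opposite directions with E2 in ERb and ERa. The phosphatase gene ALPP changed by -1.28 and 2.43, CLIC3 by -1.21 and 2.18, CA2, a carbonic anhydrase, by 1.64 and -0.93, and EDN1, which encodes endothelin 1, by 0.83 and -1.26. They are among 121 probe sets called in both lines with opposite signs.

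Ribosomal protein genes shifted by camera with 4HT in ERa (median log2 change -0.14, adjusted p = 0.000144), but 0 of 36 members were called, 6 were lower at an unadjusted p under 0.05, and the adjusted p = 0.38 with an estimated correlation. Its median was 0.03 with quantile normalization. In ERb the list shifted by camera toward lower values with E2 (2 of 36 called, 9 lower at an unadjusted p under 0.05, adjusted p = 0.00739, and adjusted p = 0.587 with an estimated correlation) and toward higher ones with 4HT (0 called, 4 at an unadjusted p under 0.05, adjusted p = 0.0166, and adjusted p = 0.664 with an estimated correlation). Fry, which tests against no change, gave this list no p under 0.05 for one direction in the 6 comparisons (smallest 0.0655) and 0.0483 for either direction with E2 in ERb. Of 27 lists 14 had no call in the 6 comparisons of a ligand with control, with a smallest adjusted p of 0.0524, for heat shock and chaperone genes. Of their 84 tests 9 had an unadjusted p under 0.05 by camera and 42 by fry. The others were AP-1, apoptosis, bone matrix, cholesterol synthesis, endothelial, hypoxia, growth factor, interferon, leukocyte, metallothionein, mitochondrial respiratory chain, nuclear receptor and p53 target lists. Erythroid markers were not tested as a list, since 1 of 15 genes passed the filter.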
